A study of Sus scrofa with 2 samples.

How the data were processed

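The series holds 2 libraries of pig endometrium, made by enzyme digestion of tissue and 10x droplet capture of the 3' ends of transcripts, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, that is, counts of distinct molecules, and the values tested as whole numbers. Cell Ranger 6.1.0 made them, per the file headers, whereas the submitters' processing notes name Cell Ranger 2.1.1. The aligner settings, whether intron reads were counted, and the genome build are not given in the sources used here. The matrices hold called cells, and the lowest barcode total was 500 UMIs in both libraries. Of 26881 genes, 16128 had an identifier without a symbol. Symbols were taken from the deposited feature tables, rows of the 50 symbols present on several rows were summed, and named results cover 10753 rows with a symbol, which took 72.1% and 71.0% of UMIs. Paralogs whose reads the counting could split are uncertain.

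Groups came from the sample titles. The gestation days in the design text could not be tied to a library by a label, so the comparison is between libraries. Barcodes with at least 500 UMIs and 200 genes were kept, which removed 5 and 1 barcodes. A planned limit on mitochondrial UMIs was not applied, because 0 mitochondrial gene names were found. Doublets were called in each library with Scrublet in scanpy 1.11.5 and removed: 1105 barcodes (11.0%) and 2414 barcodes (16.0%). Counts were scaled to 10000 UMIs per cell and log transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 (igraph 0.11.9, seed 1), without batch integration. Epithelial and stromal cells were reclustered with 20 components at resolution 0.5.

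Clusters were named as X-like from markers fixed before the data were examined, of which 135 of 215 entries had a symbol. A scoring rule was chosen after seeing the data. It took the mean log2 fold of a class's markers against the other cells of the library holding most of the cluster, with a pseudocount of 20 CPM. A name needed at least 3 markers, a mean of at least 0.5 and a margin of 0.25 over the next class. T cell and NK cell markers were joined. Clusters led by cell cycle genes, or with few UMIs and none of their own markers in the lead, stayed unnamed, and 26 of 30 clusters were named. Cells in no class were 1.72% of library 1 and 15.5% of library 2.

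With 1 library per group there was no test, and cells were not used as replicates. Shares have exact Clopper-Pearson 95% intervals. UMIs were summed per library and class and given as CPM with exact Poisson 95% intervals, and log2 ratios have exact conditional binomial intervals. Counts under 3 were set to 3 in ratios, and a ratio against 0 UMIs is given as a bound at that floor, which is about the one-sided 95% Poisson limit of a count of 0. A two-sided interval gives a lower bound. Cells are correlated and droplets hold free RNA, so all intervals cover counting error only. Named genes were chosen by a rule fixed in advance, in classes with at least 100 cells in each library. A gene needed a symbol, at least 100 CPM where higher, and at least 50% of the highest CPM of any class of at least 50 cells in that library. The 10 highest and 10 lowest ratios were taken in epithelial and stromal cells and 5 of each elsewhere, which gave 90 entries. ESR1, PGR, SPP1, PTGS2, LIF, FGF7 and MUC1 were fixed as well, and 1 further fixed gene is not reported here. For each of 18 fixed gene lists, the median log2 ratio of members with at least 10 UMIs was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. Of the list entries outside the ribosomal protein list, 378 of 547 had a symbol. List examples are the 3 members with the largest ratios among those with at least 50 CPM.

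The interval and list steps were tested on simulated data. For the stromal comparison, with 2922 genes, 100% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold were recovered, and 95.3% of intervals held the true ratio. The epithelial comparison, with 2606 genes, gave 100%, 100% and 95.4%. Unchanged lists lay outside the band in 6.5% and 4% of draws. The simulated counts had Poisson noise only and the list values were drawn independently, so these rates do not cover genes that vary together. The naming step recovered 5 of 5 simulated clusters, whose markers were raised 8-fold. Real named clusters had mean marker log2 folds as low as 0.93, in cluster 8, so weaker clusters were not tested. The alternatives were a stricter cell filter (1000 UMIs, 500 genes), doublets kept, separate clustering of the libraries, other resolutions, clustering without stress and ribosomal genes, TMM scaling from edgeR 4.0.16 in R 4.3.3, cells weighted equally, cells thinned to 1000 UMIs, and list members from 1 or 50 UMIs. TMM scaling would add 0.26 to every log2 ratio in epithelial-like, 0.20 in macrophage-like and 0.14 in ACKR1-high cells. Thinning left out 26 of 199 and 6 of 2438 epithelial-like cells, and 165 of 2328 and 33 of 2183 stromal cells.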

Results

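Droplet single-cell RNA sequencing was carried out on 2 libraries of the endometrium, the inner lining of the uterus, of Yorkshire sows after artificial insemination. The study set the pre-receptive endometrium against the receptive one, and its design names 1 sow at day 7 and 1 sow at day 13 of gestation. The labels used here name the libraries only endometrium1 and endometrium2 and do not say which library came from which day. They are therefore called library 1 and library 2, and no stage is assigned to either. Each group held 1 library from 1 animal, so no difference below has a replicate check and none was tested. Intervals cover counting error only. Library 1 held 10045 barcodes with 45388759 UMIs, a median of 3431 UMIs and 1716 genes per barcode. Library 2 held 15093 barcodes with 87514969 UMIs, a median of 4335 UMIs and 2188 genes. After filters and removal of called doublets, 8935 and 12678 cells remained.

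The first comparison asked which cell types each library held. Epithelial-like cells made up 2.23% of library 1 (199 cells, 95% Clopper-Pearson interval 1.93 to 2.55%) and 19.2% of library 2 (2438 cells, 18.5 to 19.9%). Ciliated epithelial-like cells were 0.403% of library 1 (36 cells) and 4.60% of library 2 (583 cells). Smooth muscle or pericyte-like cells were 30.2% of library 1 (29.3 to 31.2%) and 10.4% of library 2 (9.89 to 10.96%). Stromal fibroblast-like cells were 26.1% (25.1 to 27.0%) and 17.2% (16.6 to 17.9%). T or NK cell-like cells were 5.32% of library 1 and 6.57% of library 2, and macrophage, monocyte or dendritic cell-like cells were 1.98% and 4.08%. B cell-like cells numbered 7 and 124, plasma cell-like cells 85 and 86, and lymphatic endothelial-like cells 210 and 77. No cluster met the markers of neutrophils, mast cells, erythroid cells, mesothelium, Schwann cells or conceptus trophoblast. Cells were named by whole clusters, so cells of these types inside other clusters would not have been counted.

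**Figure D1:**
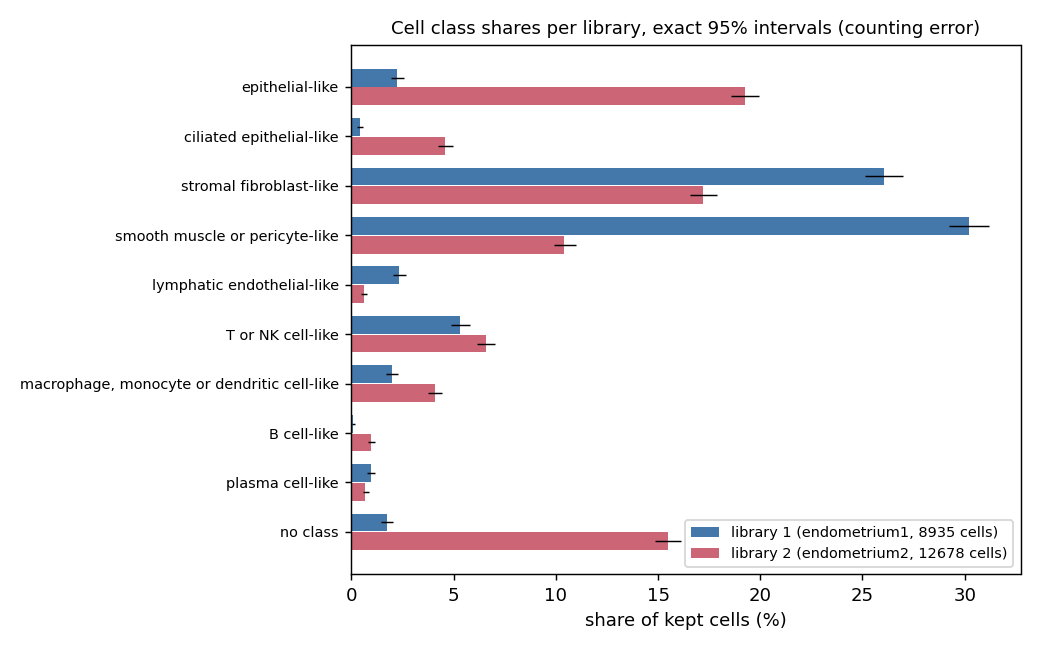
Horizontal bars give the share of kept cells (%) in each named class for library 1 (8935 cells) and library 2 (12678 cells), with exact 95% binomial intervals as error bars; blood endothelial clusters are not drawn. Epithelial-like cells were 2.23% of library 1 and 19.2% of library 2, and cells in no class were 1.72% and 15.5%.

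Different clusters held most of the epithelial-like, stromal, muscle, blood endothelial and T or NK cell-like cells in each library. Macrophage-like cells lay mainly in cluster 7 in both (171 and 463 cells). Ciliated, lymphatic, B and plasma cell-like cells each formed a single cluster shared by both libraries. Of 30 clusters, 24 took over 90% of their cells from 1 library, so such a cluster may be that library rather than a cell type. The epithelial-like class was cluster 13 in library 1 and mainly clusters 26 and 27 in library 2. The stromal class was clusters 0 and 10 in library 1 and clusters 25 and 28 in library 2. Muscle or pericyte-like cells were clusters 4, 8 and 9 in library 1 and clusters 24 and 29 in library 2, and T or NK cell-like cells were mainly cluster 6 against clusters 15 and 16. Blood endothelial-like cells were compared by cluster, because cluster 21 had KLRF1, a natural killer cell receptor gene, and none of its own class markers among its 10 leading genes. The clusters highest in ACKR1, a chemokine-binding receptor of venules, were cluster 1 (19.7% of library 1) and cluster 21 (10.0% of library 2). Those highest in SEMA3G were cluster 2 (8.95% of library 1) and cluster 18 (2.17% of library 2). Cluster 20 held 7.84% of library 2 and 2 cells of library 1. These pairs depended on how finely the cells were divided. At resolution 2.0 a separate cluster of 1145 cells of library 1 was led by PLVAP, TM4SF18 and APLNR among others, and the ACKR1-high shares were 11.4% and 10.4%. With called doublets kept the SEMA3G-high shares were 8.03% and 6.93%. Cells in no class were 1.72% of library 1 and 15.5% of library 2. The muscle difference of -19.8 percentage points was -10.3 with called doublets kept, and the stromal difference of -8.84 points was -13.8 at resolution 2.0. In these 2 settings a cluster led by SULT1E1, ACTG2 and CNN1, with 634 and 649 cells of library 1, was named stromal although its 10 leading genes held 2 markers of other classes and 0 of its own. Those values therefore carry a change of name as well as of cells. In the clustering used here, cluster 8, with 534 cells of library 1, carried the muscle genes ACTG2, CNN1 and DES beside SULT1E1 and C7, and its name as muscle rather than stroma is uncertain.

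Gland secretory genes set the epithelial-like cells of library 2 apart. In library 1 this class was the 199 cells of cluster 13. In library 2 it pooled 1491 cells of cluster 26, 894 of cluster 27 and 53 of cluster 13. The epithelial values here and below may therefore compare different mixes of epithelial cells, which was not told apart from a change within a cell type. ACP5 (ENSSSCG00025019530), which encodes the iron-binding secreted phosphatase uteroferrin, had 3.87 CPM, its UMIs scaled to a common total per class and library, in library 1 and 19001 CPM in library 2. Its log2 ratio of library 2 over library 1 was 12.26 (95% counting interval 11.46 to 13.22). UABP-2 (ENSSSCG00025016816), a uteroferrin-associated protein gene, had 0 UMIs in library 1 and 7241 CPM in library 2, at least 7492-fold higher with a floor of 3 UMIs over the class. The V-ATPase subunit gene ATP6V1C2 also had 0 UMIs in library 1 and was at least 419-fold higher in library 2 with that floor. The metalloproteinase inhibitor gene TIMP2 had 79.9 and 16306 CPM, the extracellular superoxide dismutase gene SOD3 7.41 and 1902 CPM, and the carbonyl reductase gene CBR2 1.93 and 1231 CPM. GPX3 had 1 UMI in library 1 and 398 CPM in library 2, with a log2 ratio of 8.69 at the floor of 3 UMIs and a counting interval of 7.79 to 15.58. SULT2A1, also with 1 UMI in library 1, had 245 CPM and a log2 ratio of 7.99 at that floor (7.09 to 14.88). FOSL2 and SLC35F3 had log2 ratios of 6.97 and 6.92, but FOSL2 was at 4.54 with cells weighted equally. With cells thinned to 1000 UMIs FOSL2 was at 3.19, SLC35F3 at 4.72, UABP-2 at 8.73 against 12.87, and CBR2 at 6.04 against 9.31. ATP6V1C2 and GPX3 were then at 4.65 and SULT2A1 at 3.91, while ACP5 was at 10.11, SOD3 at 6.60 and TIMP2 at 7.64. Ratios at the floor thus depend on the UMIs counted in library 1.

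Other genes were higher in the epithelial-like cells of library 1. CYP26A1, the enzyme that degrades retinoic acid, had 199 CPM in library 1 and 0.338 CPM in library 2, 589-fold lower (log2 ratio -9.20, interval -10.52 to -8.15). The water and glycerol channel gene AQP3 was at 2503 and 64.0 CPM, 39.1-fold lower in library 2. SLCO1A2, OPTC and PDZK1 were 48.7-fold, 43.7-fold and 42.3-fold lower. RLBP1, JPH4, TMEM100, MRPS36 and the WNT inhibitor gene WIF1 were between 17.5-fold and 25.2-fold lower. These values compare 199 cells of library 1 with 2438 cells of library 2.

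**Figure D2:**
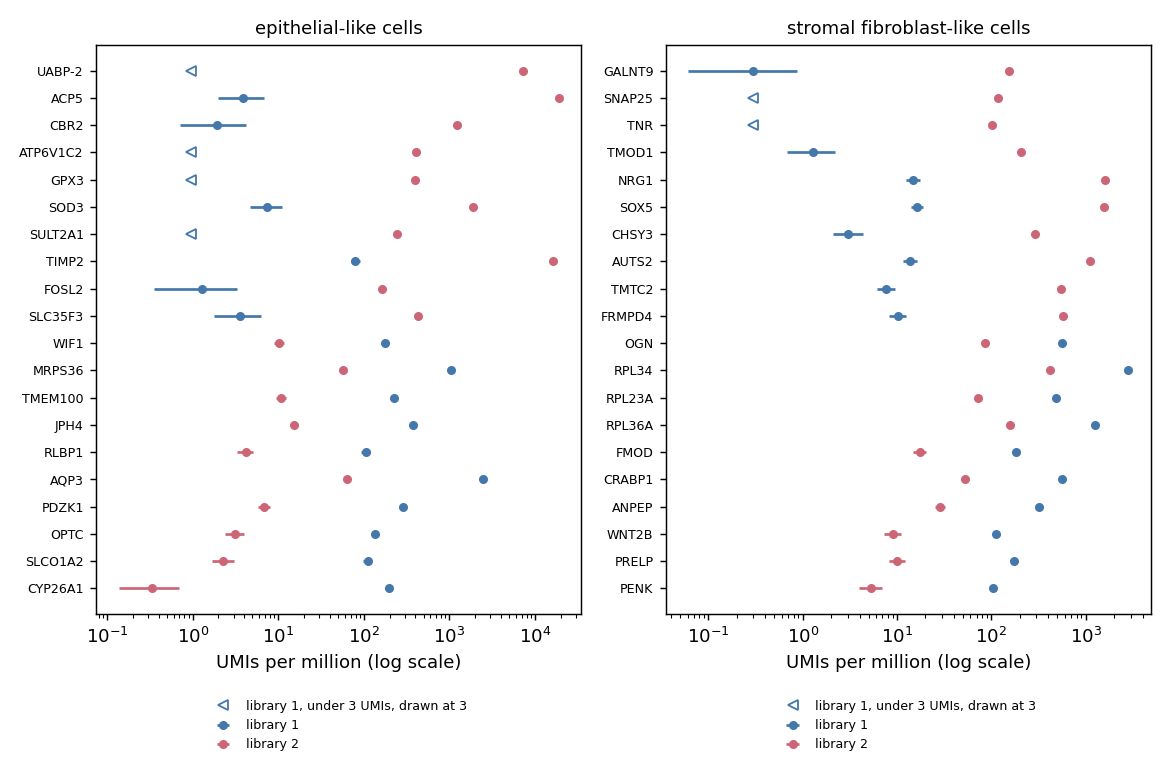
Points give CPM (log axis) in library 1 and library 2 for the 20 genes named by the fixed rule in epithelial-like cells (left) and in stromal fibroblast-like cells (right), with exact 95% Poisson intervals; triangles mark genes with under 3 UMIs, drawn at 3 UMIs. ACP5 was at 3.87 and 19001 CPM in epithelial-like cells, and NRG1 at 14.8 and 1616 CPM in stromal-like cells.

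In the epithelial-like cells 8 of the 18 fixed gene lists lay outside the central 95% of random lists. The uterine secretions list had a median log2 ratio of 1.55, with 12 of 16 measured members higher in library 2, at the 99.96th percentile of random lists matched on expression. Beside ACP5, the retinol carrier gene RBP4 was at 173 and 11018 CPM and the protease inhibitor gene SLPI at 239 and 4466 CPM. Proliferation genes were lower in library 2 in 20 of 21 members, with a median of -3.29, at percentile 0. CENPF was at 64.1 and 0.628 CPM, UBE2C at 97.3 and 1.64 CPM and TPX2 at 52.2 and 1.35 CPM, all 3 being mitotic genes. Cluster 12, led by cell cycle genes (92 and 86 cells), was left unnamed for that reason. Its cells therefore did not enter the proliferation values of any class. Growth factors and receptors had a median of 0.49 (percentile 98.8), with IGF1R at 15.1 and 402 CPM, FGFR2 at 15.1 and 361 CPM, and IGFBP2 at 10.95 and 228 CPM. Genes with very long introns had a larger epithelial median, 1.84. Steroid receptors and partners had a median of -0.96 (percentile 2.1), with PGR at 71.2 and 35.1 CPM, but NCOA1 and FKBP5 had log2 ratios of 1.45 and 1.29. Immediate early and dissociation stress genes had a median of 2.08 (percentile 100), with 25 of 30 members higher, ATF3 at 206 and 5151 CPM and NR4A1 at 20.0 and 435 CPM. Chemokines and cytokines had a median of 0.75 (percentile 99.9), which was -0.40 with cells thinned to 1000 UMIs. Their only member above the example minimum, CXCL2, was at 72.2 and 60.9 CPM.

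In the stromal fibroblast-like cells NRG1 (ENSSSCG00025052255), a ligand gene of the ERBB receptor family, had 14.8 CPM in library 1 and 1616 CPM in library 2, with a log2 ratio of 6.78 (interval 6.54 to 7.02). The transcription factor gene SOX5 was at 16.3 and 1569 CPM, and AUTS2 at 13.7 and 1113 CPM. SNAP25, a vesicle fusion gene, had 0 UMIs in library 1 and was at least 395-fold higher in library 2 with a floor of 3 UMIs. GALNT9, with 3 UMIs in library 1, had a log2 ratio of 9.02 (7.47 to 11.30), and the tenascin gene TNR, with 2 UMIs, 8.42 at the floor (7.15 to 12.05). TMOD1, CHSY3, TMTC2 and FRMPD4 had log2 ratios of 7.35, 6.56, 6.14 and 5.81. Lower in library 2 were PENK, which encodes proenkephalin (105 and 5.32 CPM), and the matrix proteoglycan genes PRELP (174 and 10.0 CPM), FMOD (180 and 17.3 CPM) and OGN (555 and 86.2 CPM). The retinoic acid-binding protein gene CRABP1 (555 and 52.8 CPM), the ligand gene WNT2B and the peptidase gene ANPEP were 10.5-fold, 12.2-fold and 11.2-fold lower. The ribosomal protein genes RPL36A, RPL23A and RPL34 were 8.03-fold, 6.81-fold and 6.74-fold lower.

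Several stromal lists lay above the central 95% of random lists, which were matched on CPM only. Genes with very long introns had a larger stromal median, 2.86. Growth factors and receptors had a median of 1.08 (percentile 98.9), with IGF1R at 21.9 and 238 CPM and FGF2 at 31.3 and 190 CPM, although IGFBP6 was lower at 680 and 117 CPM. Receptivity signalling had a median of 1.05 (percentile 98.5), with BMPR2 at 46.2 and 225 CPM and FOXO1 at 70.7 and 191 CPM. Its hedgehog pathway member GLI1 went the other way, at 58.6 and 2.66 CPM. Interferon response genes had a median of 0.90 (percentile 97.9), with IRF1 at 37.3 and 477 CPM and MX2 at 10.9 and 104 CPM. Solute, ion and calcium transport had a median of 1.00 (percentile 98.6), with the glucose transporter gene SLC2A3 at 33.2 and 187 CPM, and chemokines and cytokines a median of 0.88 (percentile 98.6), with CCL2 at 18.1 and 204 CPM. Stress and immediate early genes had a median of 1.08 (percentile 99.3), with the heat shock gene HSPH1 at 141 and 1886 CPM. Collagens and matrix genes had a median of -0.61 (percentile 1.45): COL3A1 was at 24719 and 6396 CPM, while the matrix genes POSTN and THBS1 went the other way and were higher in library 2.

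In smooth muscle or pericyte-like cells CCL2 was at 113 and 2508 CPM, CXCL2 at 64.6 and 1060 CPM and IL6 at 2.93 and 83.2 CPM. The chemokine and cytokine list had a median of 0.80 (percentile 99.6), the stress list 1.14 (percentile 99.99), the transport list 0.75 (percentile 99.0) and the interferon list 0.50 (percentile 98.2). The orphan nuclear receptor gene ESRRG and the calcium channel gene CACNB2 were 119-fold and 83.8-fold higher, FAM180A, CHSY3 and MAGI2 between 53.2-fold and 79.3-fold higher. The galanin receptor gene GALR1 was 7.86-fold lower, PCP4 7.62-fold lower, and ENC1, COX7A1 and PI15 between 4.36-fold and 4.66-fold lower. ACKR1-high endothelial cells (cluster 1 against cluster 21) had KLRF1 at 1.82 and 712 CPM, the transcription factor gene CEBPD at 54.4 and 1679 CPM, the histone demethylase gene KDM5B at 64.3 and 1992 CPM, and LRMDA and NMT2 at 77.8-fold and 28.5-fold higher levels. Among their lower genes were RPL23A, RPL34, RPL37A, RPLP2 and TOMM7, all between 4.50-fold and 5.04-fold lower. Their interferon list had a median of 0.93 (percentile 99.8), with MX2 at 61.0 and 741 CPM, and chemokines and cytokines a median of 0.71 (percentile 98.2). The angiogenesis list was lower in library 2 in ACKR1-high cells (median -0.60, percentile 0.08) and in SEMA3G-high cells (cluster 2 against cluster 18, median -0.64, percentile 0). Neither pair held cluster 20, which was led by FLT1, KDR and PLVAP in library 2, whereas cells of library 1 led by those genes lay in clusters 1 and 2, so the pairs hold different mixes of endothelial cells. FLT1, a VEGF receptor gene, went against its list in ACKR1-high cells at 281 and 653 CPM. In SEMA3G-high cells the apelin receptor gene APLNR was at 104 and 2.56 CPM, CXCL12 at 626 and 103 CPM, TM4SF18 at 214 and 27.6 CPM and AQP1 at 1632 and 306 CPM. The log2 ratio of APLNR, -5.34, was -1.77 with doublets kept and -1.85 with separate clustering, and that of TM4SF18, -2.96, was -0.94 and -1.50. CXCL12 was at -2.60, and at -3.66 with doublets kept, and AQP1 at -2.42, and at -1.56 with separate clustering. Higher there were LRMDA, SOX5, NEIL3, CCSER1 and PDE4D, between 34.4-fold and 73.4-fold. The stress list had a median of 0.48 (percentile 98.1) in those cells.

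Macrophage, monocyte or dendritic cell-like cells had CXCL10 at 188 and 3381 CPM, but CXCL9 at 399 and 39.8 CPM. CXCL11 had 95 UMIs in library 1 and 3 UMIs in library 2, a log2 ratio of -6.74 (-9.05 to -5.15). With cells thinned to 1000 UMIs CXCL11 was at -3.38, and CXCL9 at -1.71 against -3.32. The interferon list as a whole had a median of 0.64 (percentile 99.4), and proliferation genes a median of -1.06 (percentile 0.01) with 19 of 20 members lower. Dividing cells gathered in cluster 12 did not enter that proliferation value. Matrix proteases and inhibitors had a median of -0.96 (percentile 0.445), with MMP14 at 77.9 and 17.3 CPM but the inhibitor gene TIMP1 at 266 and 1386 CPM. LRMDA, DYNC1I1, FRMPD4 and KDM5B were between 30.7-fold and 89.7-fold higher and ZNRF1 had 1 UMI in library 1 and 159 CPM in library 2. RNF128, MAGED2 and ARHGAP20 were between 9.77-fold and 11.3-fold lower. T or NK cell-like cells had KDM5B at 62.7 and 1908 CPM. Its log2 ratio of 4.93 there was nearly that in macrophage-like (4.94) and ACKR1-high cells (4.95), so it was not particular to 1 class. The transcription factor gene BCL11B had 3 UMIs in library 1 and 115 CPM in library 2, a log2 ratio of 4.72 (3.15 to 7.01), and SLC1A2, AGPAT4 and FAM185A also had 1 to 3 UMIs in library 1. S100A4 was 6.52-fold lower, the mitochondrial genes TOMM7 and COX7B 4.85-fold and 4.12-fold lower, the cytokine signalling inhibitor gene CISH 4.83-fold lower and TMSB10 4.21-fold lower. Proliferation genes had a median of -0.42 (percentile 1.33) and the prostaglandin list, with 6 measured members, a median of 1.37 (percentile 98.8), which were 0.13 with doublets kept and -1.01 with members from 1 UMI. Uterine secretion genes also lay high in T or NK cell-like cells (median 1.34, percentile 99.8) and macrophage-like cells (median 0.80, percentile 98.7; -0.014 with doublets kept), with RBP4 at 1383 and 659 CPM in library 2. Their epithelial level there was 11018 CPM. Per cell of library 2, ACP5 was at 4.00 UMIs in T or NK and 4.07 in macrophage-like cells, much as in the other non-epithelial classes (4.30 to 4.87) and far under the epithelial 161. These list values were therefore not told apart from free RNA.

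Ribosomal protein genes and collagens were the lists below the band in all 7 compared classes. Ribosomal protein medians ran from -2.11 in epithelial-like to -0.92 in macrophage-like cells, at percentile 0 in each class. Ribosomal protein genes took 15.1% of UMIs in stromal-like cells of library 1 and 4.81% in library 2, and 23.1% and 5.92% in epithelial-like cells. Collagen and matrix medians ran from -1.15 to -0.61. COL3A1 was at 675 and 105 CPM in epithelial-like cells and 821 and 215 CPM in T or NK cell-like cells, against 24719 and 6396 CPM in stromal-like cells. Outside the stromal class these collagen UMIs were not told apart from free RNA of stromal cells. No list lay above the band in 1 class and below it in another. Adhesion and implantation (medians -0.30 to 0.60), tight and adherens junctions (0.03 to 0.96), hypoxia and glycolysis (-0.27 to 0.23) and cholesterol and steroid synthesis (-0.42 to 0.35) lay inside the band in all 7 classes.

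**Figure D3:**
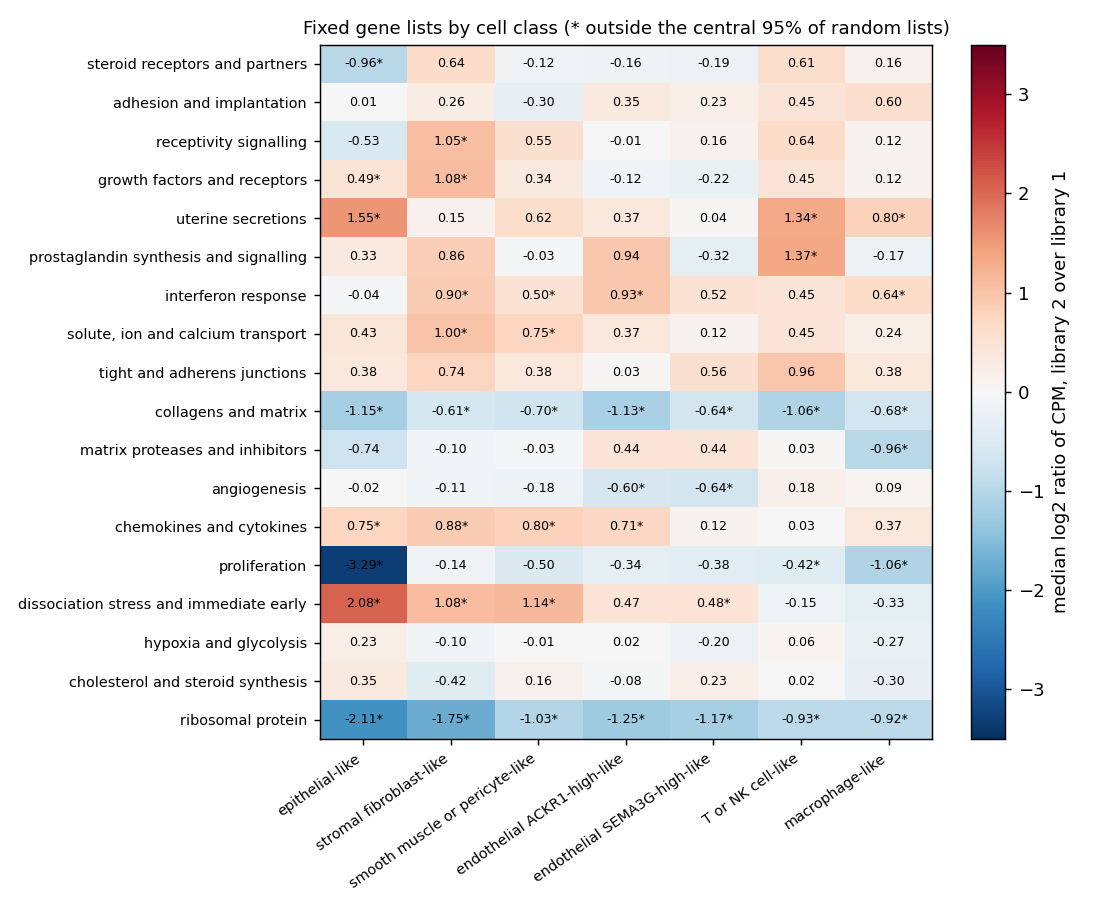
Each cell of the grid gives the median log2 ratio of CPM, library 2 over library 1, of a fixed gene list (rows) in a cell class (columns), coloured from blue (lower in library 2) to red (higher); an asterisk marks medians outside the central 95% of 10000 random lists. Ribosomal protein genes were lower in library 2 in all 7 classes, from -2.11 to -0.92, and proliferation genes were at -3.29 in epithelial-like cells.

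Genes of receptivity set in advance were read in the class where each was highest in either library. The progesterone receptor gene PGR was highest in stromal-like cells, at 135 CPM in library 1 (95% Poisson interval 128 to 142) and 363 CPM in library 2 (351 to 375). The prostaglandin synthase gene PTGS2 was highest in muscle or pericyte-like cells of library 2, at 143 CPM (133 to 153), against 6.20 CPM (4.67 to 8.06) in library 1. Within library 1 macrophage-like cells had more PTGS2, at 55.2 CPM (38.2 to 77.1). SPP1, which encodes the adhesion protein osteopontin, was highest in SEMA3G-high endothelial cells of library 1, at 298 CPM (281 to 316), against 51.9 CPM (41.2 to 64.5) in library 2. Within library 2 macrophage-like cells had more SPP1, at 216 CPM (197 to 237). LIF had 0 UMIs in epithelial-like cells of library 1 and 9.80 CPM in library 2, at least 10.1-fold higher with the floor of 3 UMIs. ESR1 and MUC1 were highest in cluster 23, an unnamed cluster found in library 2 (1390 and 24.9 CPM). For MUC1 this rests on 13 UMIs, with a 95% Poisson interval of 13.2 to 42.5 CPM that holds its epithelial value in library 2. In epithelial-like cells ESR1 was at 246 and 294 CPM and MUC1 at 1.93 and 23.6 CPM. ESR1 differed more in stromal-like cells (220 and 764 CPM) and muscle-like cells (381 and 788 CPM), and it was lower in library 2 in no compared class. FGF7 has no row under its symbol and was not analysed here.

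Reclustering the epithelial-like and ciliated cells together gave 11 subclusters, and the stromal class gave 8. In both families 0% of cells lay in a subcluster with at least 10% of its cells from each library. Library 1 gave only 199 epithelial-like and 36 ciliated cells of the 3256 in the epithelial family. Evenly mixed epithelial subclusters would therefore mostly fall under the 10% bound too, so the epithelial value says less about mixing than the stromal one. Cluster 13 of the joint clustering, with 199 and 53 cells, did lie over that bound, so some mixing could have shown. A subcluster of 47 cells, 1.56% of the epithelial cells of library 2 (1.15 to 2.06%), was led by UPTI, a uterine plasmin and trypsin inhibitor gene, at 25016 CPM. It also held SPP1 at 693 CPM, PTGS2 at 434 CPM and STC1 at 443 CPM, genes chosen after their values were seen. A subcluster of 16 cells in library 1 had UPTI at 1389 CPM, PTGS2 at 33.0 CPM and SPP1 at 4.71 CPM, the latter from 1 UMI. Another 71 cells of library 2 were led by CCL5, CCL4 and PTPRC, which are leukocyte genes, and 123 cells with a median of 16182 UMIs by LDB2 and EBF1.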

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

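The tests on clusters 22 and 23 were chosen only after the clusters' sizes, leading genes and lack of markers had been seen. Clusters outside the named classes carried a signal that the comparisons do not use. Cluster 22 held 12.5% of the kept cells of library 2 and cluster 23 held 2.33%, with 0 cells of library 1 in either. In library 1, cluster 12 held 1.03% and cluster 5 held 0.694% of kept cells. Cluster 12 was led by CENPF, UBE2C and other mitotic genes and also held 86 cells of library 2. Cluster 5 had 62 cells and was led by IL13RA2 and RGS5.

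Clusters 22 and 23 had few UMIs per cell. Their median UMI counts were 1087 and 1601, and ribosomal protein genes took 2.39% and 1.77% of their UMIs. Empty droplets holding free RNA remain open. In cluster 22 the stromal, muscle and endothelial markers lay below the level of the whole library, with a median log2 of -1.55 over 34 markers, but free RNA need not have that composition and no empty droplets were there to measure it. ACP5 was at 6039 CPM and RBP4 at 2955 CPM in this cluster, against 19001 and 11018 CPM in epithelial-like cells of library 2. The CPM of free RNA rises where cells hold few UMIs, so these values do not tell secretory expression from free RNA. Nuclei or broken cells of the epithelium remain open as well. Genes with very long introns lay at percentile 99.92 against epithelial-like cells of library 2, but the 6 epithelial markers had a median log2 of only 0.22 over the library, short of the bound of 0.5. A state of the tissue at the sampled stage was not tested.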

How the results depend on the processing

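All 40 alternative values of the share differences kept their sign, and 20 stayed within the counting interval. The epithelial difference of 17.0 points was 18.3 with the stricter filter, 13.1 with doublets kept and 22.3 with separate clustering. With separate clustering 3115 cells of library 2 were named epithelial-like rather than 2438, and 1232 rather than 1965 were in no class. The value of 22.3 may therefore carry a change of name. The ciliated one of 4.20 points was 4.91 with the stricter filter and 5.33 with doublets kept. With the stricter filter 0 cells of library 1 were named ciliated, although only 5 of the 36 had under 1000 UMIs. Epithelial-like cells of library 1 were then 203 rather than 199, so the ciliated value carries a change of name. The T or NK difference of 1.25 points was 1.95 with the stricter filter. The muscle difference of -19.8 points was -14.9 at resolution 2.0, -10.3 with doublets kept and -14.5 without stress and ribosomal genes in clustering. The stromal one of -8.84 points was -13.8 at resolution 2.0. Part of these moves is a change of name: the cells led by SULT1E1, ACTG2 and CNN1, muscle-like in cluster 8, were named stromal at resolution 2.0 (649 cells of library 1) and with doublets kept (634), each time with 2 markers of other classes and 0 stromal ones among the 10 leading genes. Without stress and ribosomal genes 517 such cells stayed unnamed. The ACKR1-high difference of -9.67 points was -0.97 at resolution 2.0, -7.31 with the stricter filter, -7.45 with doublets kept, -1.02 with separate clustering and -6.70 without stress and ribosomal genes. The SEMA3G-high one of -6.78 points was -2.27, -7.57, -1.10, -3.32 and -1.93 in the same order. The count of lists outside the band was 8 rather than 5 in T or NK cells with separate clustering, and 3 rather than 6 in macrophages after thinning. The 90 named entries kept their direction in the 6 alternatives run, but 109 of their 540 values moved beyond the counting interval. They were picked for the largest ratios in these same data, so a reversal was unlikely from the start and kept direction is no independent check. FOSL2 in epithelial cells (6.97) was 3.19 after thinning, CXCL11 (-6.74) and CXCL9 (-3.32) in macrophages were -3.38 and -1.71 after thinning, and AGPAT4 in T or NK cells (4.65) was 2.16 with doublets kept. Of 336 list medians, 48 moved and 7 changed sign. Chemokines in epithelial cells (0.75) were -0.093 with cells weighted equally, -0.40 after thinning and -0.17 with doublets kept. In T or NK cells the prostaglandin list (1.37) was -1.01 with members from 1 UMI and proliferation (-0.42) was 0.13 with doublets kept. Uterine secretions in macrophages (0.80) were -0.014 with doublets kept and -0.037 with members from 1 UMI. The cause was not tested. TMM scaling cannot change a list's percentile, since it shifts all genes of a class alike. The share of cells in mixed subclusters stayed at 0% in every setting run, which speaks to a split by library mainly in the stromal family. The mitochondrial limits were not run. No paired analysis was possible because each group has 1 library. Depth limits the immune classes of library 1 most, with 616479 UMIs in macrophages and 685871 in T or NK cells, against 3104080 in epithelial cells.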

Other observations

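The tests on long-intron genes, on depth, on shares of epithelial RNA, on UMIs per cell and on the ratio of RBP4 to ACP5 were chosen only after the result was seen. The genes described first, from IL6R to SLPI, were chosen from the fixed lists after their values were seen, and no group of them was tested. The receptivity signalling list lay inside the band in epithelial-like cells (median -0.53), with 15 of 23 members lower in library 2. Its member IL6R was at 1.61 CPM in library 1 and 343 CPM in library 2, and IL6ST, the shared signalling subunit gene, at 34.5 and 909 CPM. The transcription factor gene FOXO1 was at 27.7 and 562 CPM. The calcium-binding protein gene S100G was at 54.1 and 1.30 CPM, and the sodium pump subunit gene ATP1B1 at 490.0 and 60.2 CPM. ANGPTL4, an angiopoietin-like gene, was higher in library 2 in stromal-like cells (26.7 and 170.5 CPM), muscle-like cells (16.3 and 95.1 CPM) and ACKR1-high cells (22.3 and 63.6 CPM).

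The adhesion gene ICAM1 was at 15.7 and 232 CPM in muscle-like cells and 216 and 993 CPM in macrophage-like cells, and VCAM1 at 34.4 and 239 CPM in ACKR1-high cells. SPP1 was higher in library 2 in macrophage-like cells (60.0 and 216 CPM), opposite to its direction in SEMA3G-high cells. SLPI was at 684 and 309 CPM in SEMA3G-high cells, opposite to its epithelial direction, in clusters that hold different mixes of endothelial cells.

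Ribosomal protein genes were lower in library 2 in all 7 classes. With every cell thinned to 1000 UMIs the highest class median stayed at -0.84. Thinning keeps each gene's expected share of a cell's UMIs, so this cannot decide on a difference in UMIs per cell. A few secretory genes taking the UMIs was argued against, since the highest class median was -0.94 without the 20 most abundant genes. More unspliced or nuclear RNA, or introns counted, in library 2 is a candidate explanation: a list of 75 genes with very long introns, from which genes already named were left out, had measured members that lay above the central 95% of random lists in 7 of 7 classes. Between 23 and 40 of the 75 were measured in a class, 38 of them in epithelial-like cells. That list was written after the leading genes of the clusters had been seen, and some of its members, such as CNTNAP2 and PRKG1, were among them. Its medians ran from 1.84 in epithelial-like to 2.86 in stromal-like cells. Gene lengths in the annotation used were not checked, and the stage, the animal and the library cannot be told apart here, so leading genes such as SOX5, NRG1, AUTS2 and LRMDA, and lists higher in library 2, may share this source.

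Uterine secretion genes were found in classes other than the epithelium of library 2. ACP5 was at 950 CPM in stromal-like and 2208 CPM in T or NK cell-like cells, 5.00% and 11.6% of its epithelial level. An equal share of epithelial RNA in each class was not settled, because the largest share was 3.06 times the smallest for the median of 5 genes, between the bounds of 3 and 10. Shares of CPM also rise where cells hold few UMIs. Of the 5 genes, CTSL was at 433 CPM in stromal-like and 220 CPM in epithelial-like cells of library 1. Counted per cell, ACP5 ran only from 4.00 to 4.87 UMIs over the 6 classes, against 161 in epithelial-like cells. Free RNA of 1 composition is a candidate explanation, as the ratio of RBP4 to ACP5 UMIs ran from 0.626 to 0.710 over 6 classes, a spread of 1.13-fold, against 0.580 in epithelial-like cells. In library 1, where epithelial-like cells had ACP5 at 3.87 CPM, T or NK cell-like cells had 147 CPM and macrophage-like cells 127 CPM, so epithelial free RNA does not account for ACP5 in immune cells of that library.

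The stress and immediate early list lay above the band in epithelial, stromal, muscle and SEMA3G-high cells, and inside it in ACKR1-high (median 0.47), T or NK (-0.15) and macrophage-like cells (-0.33).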
